A study of Drosophila melanogaster with 18 samples.

How the data were processed

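RNA-seq was carried out on third-instar Drosophila melanogaster larvae in which the mef2 driver, active in muscle, expressed either lacZ as a control or the kinase NUAK. A pair of preparations was sequenced, whole larvae and dissected muscle carcass, and each held a lacZ group and 2 NUAK groups. The labels put both NUAK groups under 1 overexpression genotype and name them NUAK548 and NUAK550 without saying what the numbers stand for. Each of the 6 groups had 3 libraries, 18 in all. Larvae were kept at 25 °C on cornmeal-yeast-agar food, per the labels' protocols. RNA was extracted with a column kit and libraries were made from 2.0 ug of total RNA with NEBNext Ultra II reagents, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate crosses or cultures, so every p-value measures the spread between these libraries. The labels also give no sex for the larvae. The design has no group that separates NUAK from other genetic differences between the lacZ and NUAK larvae, such as line background.

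The deposited per-library files hold raw counts per gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the BDGP6 genome with STAR 2.5.2b, counted with featureCounts of Subread 1.5.2 and compared with DESeq2. The strand setting, the annotation release and the read layout are not given in the sources used here. The authors also deposited 1 table of normalized signal per preparation. In each table the values equalled the deposited counts divided by 1 factor per library, within a relative spread of 9.87e-10 at most, for 9402 genes in muscle and 11765 genes in whole larvae. These tables left out some genes whose total counts were at or above the lowest kept, so the counts, which cover all 17411 annotated genes, were used for the tests and the normalized values for 1 alternative.

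Gene symbols came from a reference annotation of the same organism. Of the 17411 identifiers in the files, 17137 were named by the identifier itself and 220 by position, with a Jaccard index of exon overlap of at least 0.5. The remaining 54 stayed without a name and held 0.0029% of all counts. Among shared identifiers, 98.3% had the same start and end in both annotations. Coordinates are those of the deposited files.

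Depth ran from 14577914 to 22341807 counted reads per library, and the 10 highest genes held 9.87% to 13.5% of the counts in whole larvae and 14.0% to 19.6% in muscle. CPM, counts relative to the library total, were scaled with the trimmed mean of M values (TMM). Group values are means ± SD over 3 libraries. For a gene with no counts in a group, folds were computed against a floor of 3 counts over the group and are lower bounds. Floors and SDs say nothing of error shared by all libraries, and floors cover counting error only. Correlations of log2 CPM between libraries of a group ran from 0.954 to 0.979 in muscle and from 0.833 to 0.990 in whole larvae. Within groups, no library was a copy of another, since the lowest chi-square over its degrees of freedom was 37.1.

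Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after filterByExpr and TMM, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. One model per preparation took all 9 libraries in 3 groups and left 6 residual degrees of freedom, with 9821 genes tested in muscle and 12255 in whole larvae. In each, NUAK548 and NUAK550 were compared with lacZ, their mean with lacZ, and NUAK550 with NUAK548. A model of all 18 libraries (12429 genes, 12 residual degrees of freedom) tested whether the NUAK effect differed between the preparations, and how lacZ muscle differed from lacZ whole larvae. Standard errors were derived from the log2 fold change and its F statistic. All tests were two-sided. Both NUAK comparisons of a preparation use the same 3 lacZ libraries, which makes them correlated, so their overlap was set beside 100 simulations of unchanged groups with shared controls. The replicate numbers were not used as pairs, as the labels do not say that equal numbers share a batch. The count tables of whole NUAK550 carry the numbers 2, 3 and 5 in their headers, where the labels have 1 to 3. The order of libraries follows the labels throughout, as do the replicate block and the check of pairs, which would differ under the header numbers.

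In all, 35 gene lists, 23 of processes and 12 of cell types, were fixed with 1015 symbols, of which 9 had no match. Each list with at least 3 tested members was tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists of that preparation. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance in 1 direction, were run beside it for the mean of the NUAK groups. The single groups were tested by camera at the preset correlation alone. Called members were counted over all genes tested and also adjusted over the list alone.

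The lists, the models, the alternatives and the rule for naming genes were set before the data were examined. The rule takes Nuak; w and y, which commonly mark transgenes; lncRNA:roX1 and lncRNA:roX2, noncoding RNAs of the male dosage compensation complex; and, per preparation, up to 12 genes higher and 12 lower in the mean NUAK comparison. The last had to be called in both NUAK groups in the same direction, with all 6 NUAK libraries beyond all 3 lacZ libraries and a mean CPM of at least 5. It further takes up to 2 called members in each direction per list, or the member with the smallest p where none is called. For NUAK550 against NUAK548, for the difference between preparations and for lacZ muscle against lacZ whole larvae, it takes the 5 called genes with the largest change in each direction at a mean CPM of at least 5. Members of lists that the text only counts are left out.

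The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, library totals without TMM, no low-count filter, a stricter filter (CPM of 5 in 3 libraries), the replicate number as a block, only the 2 groups compared, the authors' normalized values as log2 with a pseudocount of 1 in limma-trend, and leaving out each library in turn. Chosen after seeing the data were 1 model with the log2 CPM of roX1 (pseudocount 0.5) as a covariate and 1 that left out the third lacZ and the third NUAK548 library of whole larvae, which had low levels of muscle genes.

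The tests were tried on simulated counts with 200 genes changed by known folds. In muscle, the mean NUAK comparison recovered 10.4% of genes changed 1.5-fold, 49.3% at 2-fold and 89.2% at 4-fold. In whole larvae it recovered 0%, 18.5% and 62.1%, and the test of the difference between preparations recovered 4.5%, 25.4% and 65.2%. The edgeR tests made 0 to 4 false calls. A ribosomal protein list raised 1.5-fold was called by camera, by camera with an estimated correlation and by fry, with 0 other lists called. The simulated genes were drawn independently, whereas the real ribosomal list in muscle had an estimated correlation of 0.60. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.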

Results

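Messenger RNA levels were measured in third-instar Drosophila larvae that expressed the kinase NUAK from the muscle driver mef2, beside larvae that expressed lacZ from the same driver. The 18 libraries fall into 6 groups of 3: lacZ, NUAK548 and NUAK550, each as whole larvae and as dissected muscle carcass. Counted reads per library ran in whole larvae from 16870253 to 20162258 for lacZ, 16770092 to 19503216 for NUAK548 and 14931020 to 22341807 for NUAK550. In muscle they ran from 15361307 to 17400341, 14577914 to 17137278 and 16642042 to 19771226. Levels are given as CPM, mean ± SD over the 3 libraries of a group, and differences as log2 fold changes with their SE. Rises and falls are differences between NUAK and lacZ groups, which a difference in line background could also give.

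The first question was whether the overexpressed gene itself was higher. Nuak (FBgn0262617, 3R 10264306 to 10308467), which encodes an AMPK-related kinase, was higher in all 12 NUAK libraries than in any lacZ library of the same preparation. In muscle its level was 362 ± 21.1 CPM in lacZ, 2427 ± 506 in NUAK548 and 3953 ± 505 in NUAK550. This was 6.70-fold above lacZ in NUAK548 (log2 2.74, SE 0.19, adjusted p = 0.00071) and 10.9-fold in NUAK550 (log2 3.45, SE 0.19, adjusted p = 0.00016). In whole larvae Nuak stood at 99.5 ± 28.3 CPM in lacZ, 1396 ± 89.5 in NUAK548 and 2769 ± 89.8 in NUAK550. There the rise was 14.0-fold in NUAK548 (log2 3.81, SE 0.23, adjusted p = 0.0032) and 27.8-fold in NUAK550 (log2 4.80, SE 0.25, adjusted p = 0.00079). The levels of Nuak in NUAK550 and NUAK548 did not differ past the threshold, with log2 0.70 (SE 0.18, adjusted p = 0.095) in muscle and 0.99 (SE 0.21, adjusted p = 0.12) in whole larvae. Counts do not separate transgene reads from those of the resident gene.

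The groups also differed in RNAs that mark male cells. The noncoding RNA lncRNA:roX1 (FBgn0019661, X 3857230 to 3862697), part of the male dosage compensation complex, fell 4.20-fold in the mean of the NUAK groups in muscle (log2 −2.07, SE 0.23, adjusted p = 0.0015). Its level there was 428 ± 27.9 CPM in lacZ, 201 ± 83.3 in NUAK548 and 51.7 ± 3.08 in NUAK550. The fall was 8.28-fold in NUAK550 (log2 −3.05, SE 0.29, adjusted p = 0.001), and NUAK548 did not pass the threshold (log2 −1.09, SE 0.27, adjusted p = 0.058). Its partner lncRNA:roX2 fell in muscle as well (mean NUAK log2 −4.43, SE 0.40, adjusted p = 0.00079), from 8.33 ± 1.08 CPM in lacZ to 3.14 ± 1.45 in NUAK548, and to 2 counts over the 3 libraries of NUAK550. In whole larvae lncRNA:roX1 stood at 214 ± 16.6 CPM in lacZ, at 222, 26.8 and 22.9 in the first, the second and the third NUAK548 library, and at 30.9 ± 2.62 in NUAK550. That difference was not called (mean NUAK log2 −2.01, SE 0.65, adjusted p = 0.15), and the first NUAK548 library sat at the lacZ level. In whole larvae lncRNA:roX2 had no counts in NUAK550, so that lacZ was at least 103-fold higher against a floor of 3 counts over the group. The labels give no sex for any library.

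The white gene w (FBgn0003996, X 2790599 to 2796466), an eye-colour gene often carried as a transgene marker, was higher in NUAK550. In muscle its log2 fold change was 1.53 (SE 0.15, adjusted p = 0.00097) in NUAK550 and 0.30 (SE 0.14, adjusted p = 0.26) in NUAK548. The direct comparison of NUAK550 with NUAK548 was called in muscle at log2 1.22 (adjusted p = 0.0092) and in whole larvae at 1.16 (adjusted p = 0.012). In whole larvae that comparison called 1 gene in all without the second or the third NUAK548 library or the first NUAK550 library. The call of w there may therefore rest on single libraries. The body-colour gene y was too low to be tested in either preparation.

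**Figure D1:**
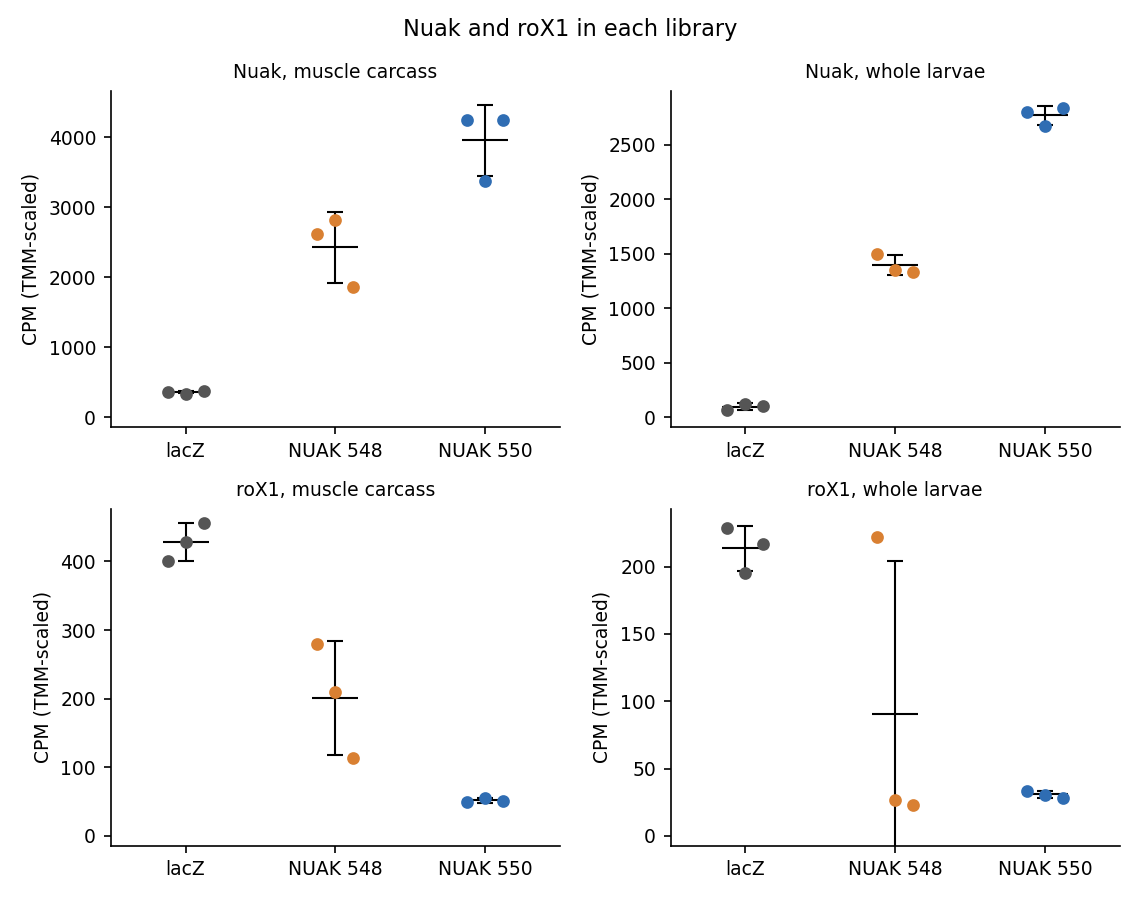
Nuak and lncRNA:roX1 levels in CPM (vertical axes) in muscle carcass and whole larvae, by genotype; points are libraries and bars with whiskers are mean ± SD of 3. Nuak is higher in every NUAK library, while roX1 is lower in every muscle NUAK library and in all whole-larva NUAK libraries but the first of NUAK548, at 222 CPM.

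Muscle overexpressing NUAK held far more RNA of 2 chaperones and of a larval actin. The small heat shock protein gene l(2)efl (FBgn0011296, 2R 23684651 to 23685543), of the alpha-crystallin family, rose from 451 ± 54.2 CPM in lacZ to 8604 ± 1244 in NUAK548 and 8668 ± 460.4 in NUAK550. This was a 19.2-fold rise in the mean of the NUAK groups (log2 4.26, SE 0.17, adjusted p = 2.1e-05). Hsp68 (FBgn0001230, 3R 24055080 to 24057310), an inducible member of the Hsp70 family, rose 5.83-fold, from 55.9 ± 33.2 CPM to 409 ± 61.6 and 259.6 ± 35.5 (log2 2.54, SE 0.35, adjusted p = 0.004). Act87E (FBgn0000046, 3R 13425983 to 13428375), an actin of larval muscle, rose 6.61-fold, from 957 ± 162 CPM to 5415 ± 2094 and 7390.1 ± 1257 (log2 2.73, SE 0.28, adjusted p = 0.0012). Its value is less certain, since lncRNA:CR45591 (log2 3.69) overlaps it on the other strand and other actin genes are close in sequence. Thor (FBgn0261560, 2L 3478434 to 3479612), the 4E-BP repressor of translation, rose 3.68-fold, from 181 ± 62.9 CPM to 739 ± 187 and 602 ± 140.2 (log2 1.88, SE 0.28, adjusted p = 0.0054).

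RyR, Ndg, rpr, Oseg5 and Dmtn were among the single genes lower in NUAK muscle. RyR (FBgn0011286, 2R 8860364 to 8888097), the ryanodine receptor that releases calcium from the sarcoplasmic reticulum, fell 5.81-fold, from 299 ± 55.5 CPM in lacZ to 28.7 ± 14.5 in NUAK548 and 92.4 ± 38.6 in NUAK550 (log2 −2.54, SE 0.33, adjusted p = 0.0032). Ndg (FBgn0026403, 2R 10313891 to 10322104), the basement membrane protein nidogen, fell 6.67-fold, from 674 ± 70.9 CPM to 98.9 ± 35.5 and 103 ± 34.4 (log2 −2.74, SE 0.24, adjusted p = 0.00078). The pro-apoptotic gene rpr (FBgn0011706, 3L 18397535 to 18398435) fell 7.73-fold, from 16.2 ± 2.93 CPM to 2.26 ± 0.829 and 1.95 ± 0.339 (log2 −2.95, SE 0.22, adjusted p = 0.00038). Oseg5, of intraflagellar transport, fell from 14.0 ± 1.66 CPM to 1.07 ± 0.318 and 0.920 ± 0.467 (log2 −3.79, SE 0.27, adjusted p = 0.00033). Dmtn (FBgn0037443, 3R 6389162 to 6405895) fell 3.24-fold, from 195 ± 18.1 CPM to 61.3 ± 11.1 and 58.9 ± 1.75 (log2 −1.69, SE 0.11, adjusted p = 0.00024). The octopamine receptor Octalpha2R (log2 −2.45), the serpin Spn47C (log2 −2.29), Dscam4 (log2 −3.72), CG43740 (log2 −3.49), CG7582 (log2 −1.99), Hydr2 (log2 −1.98) and Pif1A (log2 −1.91) also fell. For Pif1A, 88% of the exon length overlaps another gene.

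Among the genes nearly silent in lacZ muscle, mthl8 (FBgn0052475, 3L 22428 to 26308), a methuselah-like receptor, rose from 0.0827 ± 0.143 CPM to 15.5 ± 2.16 in NUAK548 and 9.87 ± 3.05 in NUAK550 (log2 7.14, SE 0.64, adjusted p = 0.00078). CG40298 rose from 0.120 ± 0.104 CPM to 6.92 ± 2.45 and 11.8 ± 2.17 (log2 6.14, adjusted p = 0.00072). CG30334 (log2 4.51), CG14022 (log2 4.21), lncRNA:CR43459 (log2 2.68), CG10226 (log2 2.62), asRNA:CR42860 (log2 2.55) and CG6972 (log2 2.55) rose too. The 75% of asRNA:CR42860 exon length shared with another gene leaves its value uncertain. From l(2)efl to CG6972, the call of each muscle gene held when each muscle library was left out in turn.

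**Figure D2:**
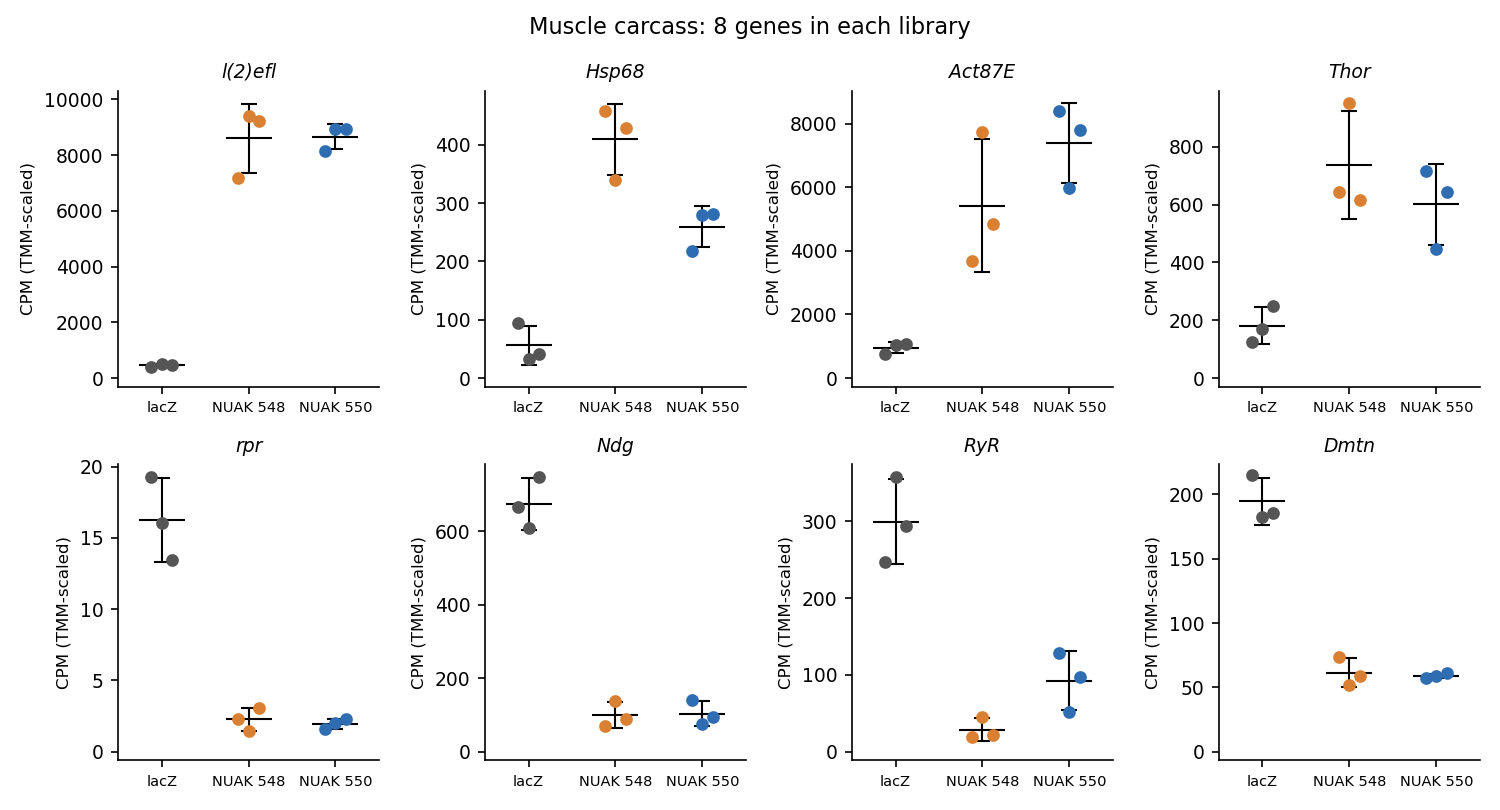
CPM (vertical axes) of l(2)efl, Hsp68, Act87E, Thor, rpr, Ndg, RyR and Dmtn in muscle carcass by genotype; points are libraries and bars with whiskers are mean ± SD of 3. The 6 NUAK libraries lie above lacZ for the first 4 genes and below it for the last 4.

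Over the 9821 genes tested in muscle, 546 differed between NUAK548 and lacZ (255 higher, 291 lower) and 1233 between NUAK550 and lacZ (633 higher, 600 lower). The mean of the NUAK groups gave 1041 (476 higher, 565 lower), of which 159 were at least 2-fold higher and 154 at least 2-fold lower. Both NUAK groups called 354 genes in the same direction (161 higher, 193 lower) and 0 in opposite directions. Independent lists would share 16.4 higher and 17.8 lower genes, and unchanged groups with the same shared controls gave a mean of 0.01 in 100 simulations, 1 at most. The simulations held no changed genes, so they do not measure what shared controls add to the overlap of lists this long. The log2 fold changes of NUAK548 and NUAK550 correlated across genes at r = 0.49, with 0.50 in the simulations, and genes are not independent replicates. Their covariance was 0.249 against a simulated 0.0774, a difference of 0.172. With 3 control libraries, the controls cannot be divided into separate sets of 2, so part of that excess is not separable from the shared controls.

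The counts depend on single libraries. The NUAK548 count was 247, 174 and 254 without the first, second and the third lacZ library, and 309 and 260 without the first and the third NUAK548 library. Without the first, second and the third lacZ library the NUAK550 count was 459, 670 and 509, and it was 590 and 403 without the first and the third NUAK550 library. The count for the mean was 410, 426 and 453 without each lacZ library and 584 without the third NUAK550 library. The shared count was 163, 134 and 166 without each lacZ library, 187 without the third NUAK548 library and 174 without the third NUAK550 library. With the roX1 level as a covariate, which nearly coincides with the groups in muscle, 0 genes were called by edgeR for the mean of the NUAK groups and 579 had an unadjusted p below 0.05.

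**Figure D3:**
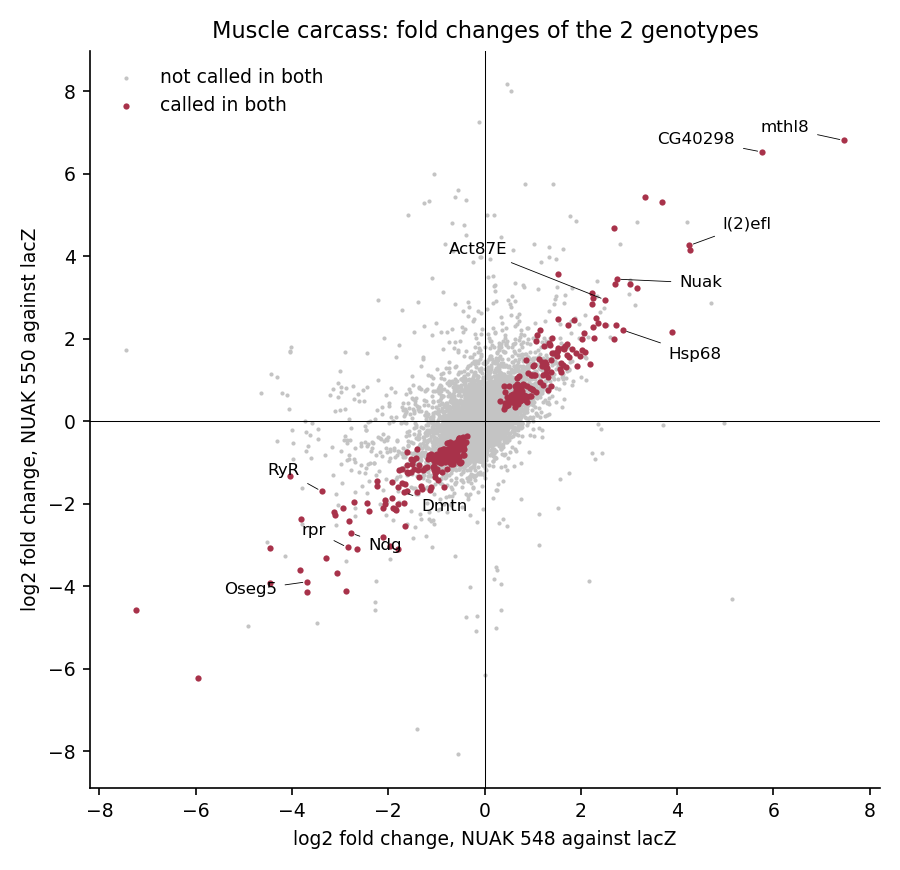
Log2 fold change against lacZ in muscle for NUAK548 (horizontal axis) and NUAK550 (vertical axis), 1 point per gene tested, with the 354 genes called in both in red. All 354 lie in the quadrants where both values have the same sign.

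Camera called 3 lists of the translation machinery higher in NUAK muscle, and none of these calls held with an estimated correlation. In all it called 11 muscle lists for the mean, and other splits of the same libraries into groups gave a median of 10. The number of called lists is thus close to what regrouping gives. Fry called the cytosolic ribosomal (adjusted p = 0.011) and nucleolar lists (0.019) higher and did not call the mitochondrial ribosomal list (0.20). Of 84 cytosolic ribosomal protein genes tested, 29 rose and 0 fell over all genes, and 71 rose adjusted over the list alone, with a median log2 fold change of 0.36. The median was 0.20 in NUAK548, where 1 member was called, and 0.51 in NUAK550, where 68 were. RpS12 stood at 523 ± 65.1 CPM in lacZ, 693 ± 68.6 in NUAK548 and 967 ± 70.2 in NUAK550 (log2 0.65, SE 0.12, adjusted p = 0.013), and RpL35 at 649 ± 51.2, 839 ± 26.2 and 1015 ± 65.4 (log2 0.51, SE 0.10, adjusted p = 0.014). Without the first lacZ library these became adjusted p = 0.064 for RpS12 and 0.068 for RpL35, and without the third 0.064 and 0.073. Camera called the list (adjusted p = 2e-24), with adjusted p = 0.81 with an estimated correlation. Of 36 nucleolus and ribosome biogenesis genes, 10 rose and 0 fell, with 19 higher and 1 lower adjusted over the list alone and a median of 0.27. Camera gave adjusted p = 3e-07, and adjusted p = 0.81 with an estimated correlation. Non1, a nucleolar GTPase gene, rose from 489 to 751 and 770 CPM (log2 0.64, SE 0.11, adjusted p = 0.009), and was lost without the first lacZ library (adjusted p = 0.052). Of 72 mitochondrial ribosomal protein genes 1 rose (1 adjusted over the list alone), mRpL11 (log2 0.91, adjusted p = 0.0057), with a list median of 0.17 and camera adjusted p = 0.0013. That became adjusted p = 0.93 with an estimated correlation, and the median was 0.26 without the second and 0.12 without the third lacZ library. The 2 NUAK groups had mitochondrial ribosomal medians of opposite sign, −0.04 in NUAK548 and 0.31 in NUAK550. With lncRNA:roX1, itself lower in the NUAK groups, as a covariate, the cytosolic ribosomal median was 0.131 (adjusted p = 0.31), the mitochondrial ribosomal call was lost (adjusted p = 0.36) and the nucleolar call held.

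Camera called none of the contractile, synaptic and adhesion lists in muscle for the mean of the NUAK groups. Of 36 sarcomere and myofibril genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.23; camera adjusted p = 0.099, and adjusted p = 0.93 with an estimated correlation). The median ran from 0.04 without the second NUAK548 library to 0.38 without the second lacZ library. By group, camera called the sarcomere list higher in NUAK550 (median 0.71, adjusted p = 0.0027) and not in NUAK548 (median −0.10, adjusted p = 1.0). Beside Act87E and Mp20, the named members were Strn-Mlck, a myosin light chain kinase gene, which fell from 357 ± 52.4 CPM to 134 ± 24.9 and 194 ± 52.6 (log2 −1.15, SE 0.19, adjusted p = 0.009), and flr, of actin disassembly, which fell from 686 ± 44.6 CPM to 307 ± 53.7 and 379 ± 32.5 (log2 −1.01, SE 0.12, adjusted p = 0.0024). Mp20, a muscle actin-binding protein gene, stood at 1660.2 ± 461, 2737 ± 1416 and 6566 ± 1163 CPM (log2 1.35, SE 0.34, adjusted p = 0.039), a call lost without any of 7 of the 9 libraries, up to adjusted p = 0.15 without the first lacZ library. Of 11 postsynaptic neuromuscular junction genes, 1 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.099). Fry called that list lower for the mean (adjusted p = 0.047), against adjusted p = 0.86 by camera with an estimated correlation. Camera at the preset correlation called it lower in NUAK548 (median −0.32, adjusted p = 0.038) and not in NUAK550 (median −0.21, adjusted p = 0.35). The glutamate receptor subunit genes GluRIIE, at 83.2 ± 15.7, 40.4 ± 8.81 and 42.6 ± 4.99 CPM (log2 −1.0, SE 0.16, adjusted p = 0.0079), and GluRIIB (log2 −0.82, SE 0.12, adjusted p = 0.0049) were among those that fell. Of 25 integrin adhesion and matrix genes, 1 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.62), with Ndg and the matrix metalloprotease Mmp2 (log2 −0.72, SE 0.12, adjusted p = 0.008) among those lower. Calcium handling and excitability genes split 4 higher and 3 lower of 13 (4 and 4 adjusted over the list alone; camera adjusted p = 0.78). Of 15 muscle identity regulators 1 fell (0 adjusted over the list alone; camera adjusted p = 0.75). The NUAK and LKB1 pathway list had 1 higher member of 15, Nuak, and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.94). Its median was −0.03 and its mean 0.19.

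Of 21 chaperone and BAG-family genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with l(2)efl and Hsp68 the largest. Camera did not call the list (adjusted p = 0.53) and fry called it higher (adjusted p = 0.0048), against adjusted p = 0.93 by camera with an estimated correlation. Its median of −0.06 differs in sign from its mean of 0.27. Of 33 autophagy and lysosome genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.37). By group, camera called the autophagy list lower in NUAK550 (median −0.27, 7 members lower and 1 higher, adjusted p = 0.0057) and not in NUAK548 (median 0.03, 1 lower and 4 higher, adjusted p = 0.37). Atg16, needed to form autophagosomes, rose from 27.9 ± 1.6 CPM to 84.0 ± 29.6 and 63.9 ± 8.54 (log2 1.39, SE 0.21, adjusted p = 0.0059). Snap29, a SNARE of autophagosome fusion, fell from 66.1 ± 4.35 CPM to 34.5 ± 0.99 and 33.4 ± 6.11 (log2 −0.96, SE 0.11, adjusted p = 0.002). Proteasome subunit genes had a median of 0.25, with 3 of 32 higher (3 adjusted over the list alone), 0 lower and camera adjusted p = 1.4e-05. That was adjusted p = 0.93 with an estimated correlation, and the medians were 0.50 in NUAK548 and −0.01 in NUAK550.

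Among the lists of stress, immune and growth regulators, camera called those of JNK and of cell cycle genes for the mean of the NUAK groups. Neither call held with an estimated correlation. In the JNK and apoptosis list, 1 of 12 rose and 2 fell (1 and 3 adjusted over the list alone; median −0.23; camera adjusted p = 0.028, and adjusted p = 0.81 with an estimated correlation). The JNK phosphatase gene puc rose from 46.1 ± 10.2 CPM to 114 ± 34.1 and 97.5 ± 9.47 (log2 1.20, SE 0.21, adjusted p = 0.011), while rpr and the Fos gene kay (log2 −0.97, SE 0.12, adjusted p = 0.0026) fell. This list was lost without the first lacZ library (adjusted p = 0.051), the third (0.057) or the second NUAK548 library (0.073). Of 13 unfolded protein and integrated stress genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.069, and 0.027, higher, in NUAK548), with Atf6, an ER stress factor, at log2 0.56 (adjusted p = 0.0074) and Irbp18, a bZIP partner of the ATF4 homologue, at −1.08 (adjusted p = 0.001). The NF-kB factor Rel rose from 159 ± 33.7 CPM to 317 ± 42.0 and 345 ± 13.9 (log2 1.05, SE 0.16, adjusted p = 0.0054), in an immune list with 1 of 24 higher and 2 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.43). Of 27 cell cycle genes, 1 rose (5 adjusted over the list alone), RnrS of ribonucleotide reductase (log2 0.71, adjusted p = 0.0069). Camera called that list (median 0.23, adjusted p = 0.0011), with adjusted p = 0.5 with an estimated correlation. Thor was the called member of 20 Myc and insulin-TOR genes (1 adjusted over the list alone; camera adjusted p = 0.51). Hippo genes had 2 of 13 higher and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.43). Ecdysone genes had 1 of 21 higher (1 adjusted over the list alone; camera adjusted p = 0.53), and antioxidant genes 3 of 21 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.7).

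Camera called 3 lists of energy metabolism lower for the mean of the NUAK groups. Glycolysis and glycogen genes had a median of −0.33, with 1 of 23 lower (1 adjusted over the list alone) and camera adjusted p = 0.018, against adjusted p = 0.93 with an estimated correlation. Oxidative phosphorylation genes had a median of −0.17, with 2 of 64 lower (0 adjusted over the list alone) and camera adjusted p = 0.023, against adjusted p = 0.93 with an estimated correlation. Its median was −0.51 in NUAK548 and 0.13 in NUAK550, and it was 0.00557 without the second lacZ library. The glycolysis median was −0.64 in NUAK548 (camera adjusted p = 0.00017) and −0.07 in NUAK550, which was not called (0.49). For the mean it ran from −0.55 to −0.17 without single NUAK548 libraries. Lipid synthesis and storage genes had a median of −0.37, with 3 of 16 lower (3 adjusted over the list alone), and among them was Lpin, which encodes lipin (log2 −0.71, SE 0.12, adjusted p = 0.008). Camera gave adjusted p = 0.023 for lipid genes, and adjusted p = 0.81 with an estimated correlation. Single libraries ended these calls. Glycolysis reached adjusted p = 0.08 without the second lacZ, 0.065 without the first NUAK548 and 0.067 without the second NUAK550 library, and the same 3 exclusions took oxidative phosphorylation to 1.0, 0.33 and 0.12. Lipid genes reached 0.074 without the third lacZ and 0.064 without the second NUAK550 library.

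**Figure D4:**
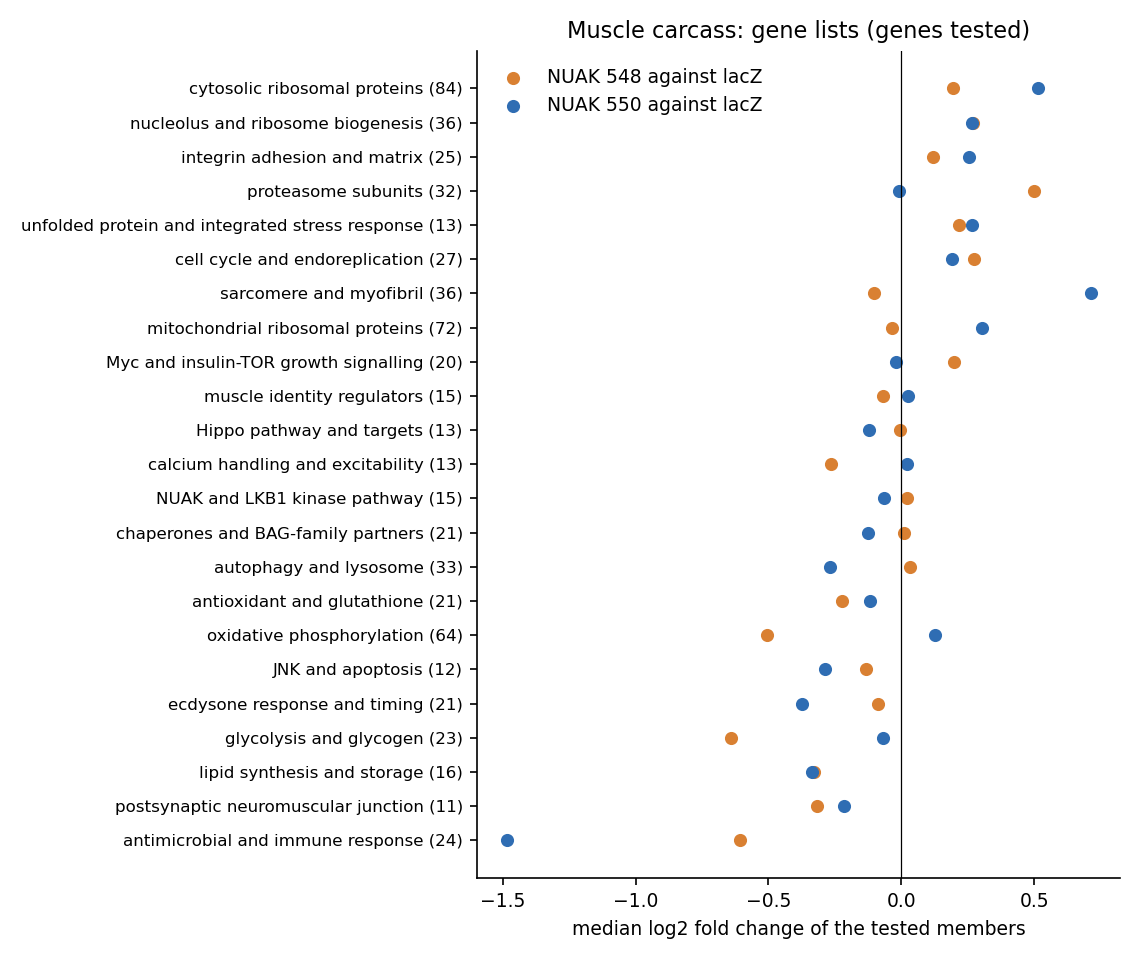
Median log2 fold change against lacZ in muscle (horizontal axis) of the tested members of the 23 process lists (vertical axis, number tested in brackets), orange for NUAK548 and blue for NUAK550. Cytosolic ribosomal proteins lie above 0 in both (0.20 and 0.51), and oxidative phosphorylation has opposite signs (−0.51 and 0.13).

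Cell type markers in the muscle preparation showed how RNA of other tissues differed between the groups, and single libraries moved some lists far. The salivary gland median ran from −3.48 without the third NUAK550 library to −0.30 without the third lacZ library. Gut genes were lower (median −1.33), with 4 of 31 called (4 adjusted over the list alone) and camera adjusted p = 0.023, against adjusted p = 0.93 with an estimated correlation. By group, camera called them lower in NUAK548 (median −2.05, adjusted p = 0.0012) and not in NUAK550 (median −0.60, adjusted p = 0.55). Without the first lacZ library the gut list reached adjusted p = 0.85 with a median of −0.0184, and without the second NUAK548 library adjusted p = 0.074. Hemocyte genes were higher (median 0.57), with 3 of 11 called (3 adjusted over the list alone) and camera adjusted p = 0.023, against adjusted p = 0.93 with an estimated correlation and 0.073 without the second NUAK548 library. Camera called the hemocyte list in NUAK550 (median 0.84, adjusted p = 0.012) and not in NUAK548 (median 0.21, adjusted p = 0.28). The hemocyte phagocytosis receptor gene NimC1 rose from 16.2 ± 2.02 CPM to 34.3 ± 10.04 and 68.7 ± 18.2 (log2 1.58, SE 0.23, adjusted p = 0.0047). Not called by camera were neuron (0 of 15 members called; adjusted p = 0.11), salivary gland (0 of 12; 0.12), testis (0 of 6; 0.62), cuticle (3 higher and 2 lower of 65; 0.64, and 0.013, lower, in NUAK548), fat body (0 of 12; 0.75), imaginal disc (0 of 12; 0.87), Malpighian tubule (0 of 8; 0.87), glia (0 of 7; 0.94) and trachea genes (1 lower of 8; 0.94). With the roX1 level as a covariate, the calls of hemocyte (adjusted p = 0.49), proteasome (0.15), lipid (0.79), JNK (0.79) and cell cycle genes (0.79) in muscle were also lost. Adjusted over the list alone, cuticle had 2 higher and 2 lower, trachea 1 lower and the other lists of that sentence 0.

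The NUAK548 and NUAK550 groups differed from each other in muscle. Listericin (2R 11241745 to 11242194), an antibacterial peptide gene, stood at 239 ± 72.6 CPM in lacZ, 273 ± 95.3 in NUAK548 and 16.9 ± 3.89 in NUAK550, so that NUAK550 was 16.2-fold below NUAK548 (log2 −4.02, SE 0.36, adjusted p = 0.005). CG13230 stood at 0.286 ± 0.243 CPM in NUAK548 and 60.2 ± 40.7 in NUAK550 (log2 7.72, SE 0.83, adjusted p = 0.0074). Mrp5, an ABC transporter gene, stood at 2.71, 13.8 and 2.59 CPM in lacZ, NUAK548 and NUAK550 (log2 −2.42, SE 0.30, adjusted p = 0.01), and its call ended without the third NUAK550 library (adjusted p = 0.065). Also named were CG11350 (log2 7.48, adjusted p = 0.012), lost without the first or the third NUAK548 library (0.072 and 0.071), and lncRNA:roX1 (log2 −1.96, adjusted p = 0.02), lost without the first NUAK548 (0.05) or the first or the third NUAK550 library (0.09 and 0.098). Less stable were the calls of Alp7 (log2 9.18, adjusted p = 0.038; 2 counts in NUAK548), Cpr47Eg (7.39, 0.047), CG13705 (7.04, 0.025), CG15282 (−2.28, 0.038) and AttA (−6.04, 0.049), whose near copy AttB makes its counts uncertain, each lost without any of 3 to 5 libraries. Without the first NUAK548 library their adjusted p was 0.16, 0.18, 0.12, 0.13 and 0.10. In all, 142 of 9821 genes were called, 92 higher and 50 lower in NUAK550. The count was 27 and 37 without the first and the third NUAK548 library, and 43 and 29 without the first and the third NUAK550 library.

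In whole larvae, mthl8 was again higher in both NUAK groups. It had no counts in lacZ, 16.4 ± 1.53 CPM in NUAK548 and 12.2 ± 3.94 in NUAK550, at least 305-fold and 227-fold higher against a floor of 3 counts over the lacZ group (adjusted p = 0.0039 for the mean). Whether NUAK or line background set its level was not tested. CG3588 (X 2919770 to 2924426) rose from 0.299 ± 0.417 CPM to 86.7 ± 47.4 and 234 ± 35.8 (log2 8.84, SE 0.86, adjusted p = 0.012). CARPB (X 9783223 to 9855449), a carbonic anhydrase-related gene, rose from 4.68 ± 1.13 CPM to 40.8 ± 12.9 and 51.4 ± 6.36 (log2 3.29, SE 0.27, adjusted p = 0.0054). GILT3, a lysosomal thiol reductase gene, rose from 5.05 ± 1.18 CPM to 20.1 ± 2.91 and 19.8 ± 3.46 (log2 1.98, SE 0.20, adjusted p = 0.015), and l(2)efl from 569 ± 123 CPM to 1347 ± 157 and 2364 ± 121 (log2 1.65, SE 0.17, adjusted p = 0.015). Lower were CG2493, from 264 ± 5.52 CPM to 129 ± 8.9 and 128 ± 6.59 (log2 −1.04, SE 0.08, adjusted p = 0.0039), the P450 gene Cyp4p2 (log2 −1.33, SE 0.11, adjusted p = 0.0054), CG3568 (log2 −1.72, SE 0.13, adjusted p = 0.0044) and CG9427 (log2 −0.81, SE 0.07, adjusted p = 0.0057). Without the second lacZ library, Nuak, mthl8 and CG2493 stayed called among these. The others then had adjusted p = 0.06 (CARPB, Cyp4p2, CG3568, CG9427) or 0.064 (CG3588, GILT3, l(2)efl). GstD10, a glutathione S-transferase gene with close relatives (log2 2.24, adjusted p = 0.015), CG11668 (log2 −1.70, adjusted p = 0.016) and CG14253 (log2 −0.84, adjusted p = 0.016) were also called, and were lost without the first NUAK550 library (0.06, 0.086 and 0.086), among others. GILT3 was also lost without the third lacZ library (0.061), and l(2)efl without the first lacZ library (0.0504) and the first or second NUAK550 library (0.0713 and 0.0532). With the replicate block the calls of CG3588 (adjusted p = 0.055), GILT3, GstD10 and CG14253 (0.067 each) were lost, and the others named here held. With the roX1 level as a covariate, 3 genes in all stayed called for the mean in whole larvae, all of them higher. The calls of the lower genes named here were thus lost in that model.

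Transcripts of the male germline were lower in 5 of the 6 NUAK libraries of whole larvae. Chosen after their values were seen, Mst87F, betaTub85D and the Y-linked kl-5 show the pattern. The testis tubulin gene betaTub85D stood at 124, 113 and 115 CPM in lacZ, at 159.8 in the first NUAK548 library, and between 0.799 and 1.44 in the other 5. The sperm gene Mst87F stood at 22.2 to 39.2 CPM in lacZ and 31.7 in the first NUAK548 library, and at 1.2 or less in the others. The axonemal dynein gene kl-5 stood at 1.9 to 3.52 CPM in lacZ, 7.31 in the first NUAK548 library and 0.147 or less in the others. On the first principal component of whole larvae, which held 81.4% of the variance, the 3 lacZ libraries and the first NUAK548 library lay at −123 to −106 and the other 5 at 83.2 to 102.

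**Figure D5:**
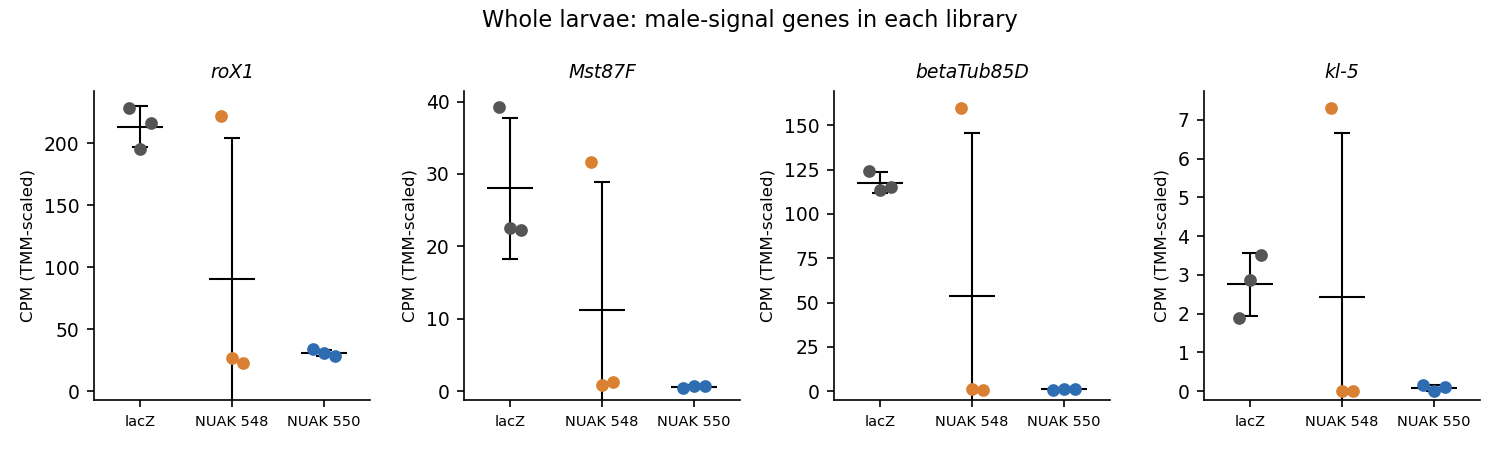
CPM (vertical axes) of lncRNA:roX1, Mst87F, betaTub85D and kl-5 in whole larvae by genotype; points are libraries and bars with whiskers are mean ± SD of 3. The first NUAK548 library lies with lacZ or above it, and the other 5 NUAK libraries lie near 0 for the last 3 genes.

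Over the 12255 genes tested in whole larvae, 19 differed between NUAK548 and lacZ (7 higher, 12 lower), 99 between NUAK550 and lacZ (73 higher, 26 lower) and 52 between the mean of the NUAK groups and lacZ (25 higher, 27 lower; 13 with the replicate block). The directions depend on the model. Fitted without NUAK548, the comparison of NUAK550 with lacZ gave 754 higher and 2257 lower. It gave 435 higher and 1687 lower with the authors' values, and the mean gave 370 higher and 1724 lower with limma-voom. Both NUAK groups called 12 genes in the same direction (6 and 6), against 0.0417 and 0.0255 for independent lists and 0 in simulations of unchanged groups with shared controls. With no changed genes, those simulations do not measure what shared controls add to this overlap. The log2 fold changes correlated across genes at r = 0.68, with 0.50 in the simulations, and their covariance was 1.22 against 0.325, a difference of 0.894. Without the first NUAK548 library, the one at the lacZ level of roX1, the counts became 2271 for NUAK548 (2096 lower), 2721 for the mean (2339 lower) and 2059 shared.

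Other single libraries moved these counts downwards. The NUAK548 count was 4 without the second lacZ library, and 8 and 10 without the second and the third NUAK548 library. The NUAK550 count was 50, 54 and 14 without each lacZ library and 14, 15 and 12 without each NUAK550 library. The count for the mean was 19, 3 and 21 without each lacZ library, 16 and 25 without the second and the third NUAK548 library, and 11, 14 and 21 without each NUAK550 library. Shared genes numbered 3 and 7 without the second and the third lacZ library, 5 and 6 without the second and the third NUAK548 library, and 6, 6 and 5 without each NUAK550 library. When the third lacZ and the third NUAK548 library, both low in muscle gene RNA, were left out together, the counts were 10, 56 and 15 for NUAK548, NUAK550 and the mean.

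In whole larvae camera called 12 lists for the mean of the NUAK groups, 9 higher and 3 lower. Other splits of the same libraries into groups also gave a median of 12 called lists. Camera sets a list against all other genes tested, and these include the male-signal genes that fell. A list called higher is therefore higher relative to that background, and how much of each call it accounts for was not tested. Fry, which looks at the members alone, called only the nucleolus list (adjusted p = 0.0013). Testis and male germline genes had a median of −3.63, with 0 of 16 called over all genes and 15 lower adjusted over the list alone (camera adjusted p = 2.9e-06). Male-share markers had a median of −3.86, with 0 of 9 called, 0 adjusted over the list alone and camera adjusted p = 0.00011. Proteasome genes had a median of −0.22, with 0 of 32 called, 0 adjusted over the list alone and camera adjusted p = 0.00031. Higher by camera were nucleolus and ribosome biogenesis (median 0.27; 1 of 36 called, 20 adjusted over the list alone; adjusted p = 1.7e-07), cell cycle (median 0.30; 0 of 27, 10 adjusted over the list alone; 1.3e-05), sarcomere and myofibril (median 0.62; 1 of 35, 2 adjusted over the list alone; 1.3e-05) and neuron genes (median 0.47; 0 of 15, 6 adjusted over the list alone; 6.7e-05). So were calcium handling (median 0.55; 0 of 13, 0 adjusted over the list alone; 0.00015), integrin adhesion (0.17; 0 of 25, 2; 0.007), Myc and insulin-TOR (0.16; 0 of 20, 0; 0.036), the NUAK and LKB1 pathway (0.22; 1 of 15, 3; 0.041) and unfolded protein genes (0.13; 0 of 13, 1; 0.049). By group, the sarcomere list was called in NUAK550 (median 1.39, adjusted p = 6e-10) and not in NUAK548 (median −0.07, adjusted p = 0.58), and the third lacZ and the third NUAK548 library were low in muscle gene RNA. With an estimated correlation none was called: adjusted p = 0.29 with an estimated correlation for nucleolus and 0.76 for the others. Cytosolic ribosomal proteins were not called for the mean in whole larvae (camera adjusted p = 0.066; median 0.08, mean −0.16), and were called higher in NUAK550 (median 0.19, 0 of 89 members called, adjusted p = 0.0015).

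Several of these list calls also rest on single libraries. Proteasome reached adjusted p = 0.14 without the first NUAK548 library, and integrin adhesion 0.12 without the first lacZ library. Myc and insulin-TOR reached 0.44 without the first lacZ and 0.083 without the third NUAK548 library. The NUAK and LKB1 pathway reached 0.33 without the first lacZ, 0.065 without the first NUAK548 and 0.072 without the third NUAK548 library. The unfolded protein call was lost without any of 6 libraries, up to 0.068 without the first NUAK548 library. Medians moved too. Without the first NUAK548 library the testis median was −6.55 and that of the male-share markers −7.14, and without the first lacZ library the medians were 0.22 for neuron, 0.34 for calcium handling, 0.07 for unfolded protein, 0.03 for Myc and insulin-TOR, 0.01 for the NUAK and LKB1 pathway and 0.0045 for integrin adhesion genes. With the roX1 level as a covariate, the calls of the testis (adjusted p = 0.19), male-share (0.92), integrin (0.089), NUAK and LKB1 (0.19), unfolded protein (0.45) and Myc and insulin-TOR lists (0.92) were lost.

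Comparing NUAK550 with NUAK548 directly in whole larvae, an amylase-related gene and a lipase gene were higher in NUAK550. Amyrel, the former, stood at 29.2, 1.89 and 38.1 CPM in lacZ, NUAK548 and NUAK550 (NUAK550 against NUAK548 log2 4.34, SE 0.37, adjusted p = 0.012). The lipase gene Lip3 stood at 5.14, 1.01 and 25.4 CPM (log2 4.64, SE 0.42, adjusted p = 0.012), and lcs at 2.78 ± 1.21, 1.56 ± 0.843 and 133 ± 26.9 (log2 6.43, SE 0.51, adjusted p = 0.012). The 1 lower gene was CG3397, at 0.189, 56.8 and 0.281 CPM (log2 −7.53, SE 0.81, adjusted p = 0.023), a call lost without any of 5 of the 6 libraries, up to adjusted p = 0.14 without the second NUAK550 library. CG10073 (log2 7.84, adjusted p = 0.044) and Obp99b (log2 4.15, adjusted p = 0.023) were higher in NUAK550, calls lost without any of 5 and 4 libraries, up to adjusted p = 0.14 and 0.10 without the third NUAK548 library, and with the replicate block (0.053 and 0.055). Of 12255 genes, 17 were called, 16 higher in NUAK550. Amyrel, Lip3 and lcs had adjusted p = 0.051 without the first NUAK550 library. Without the second NUAK548 library Amyrel and Lip3 had 0.068, and without the third Amyrel and lcs had 0.066. The count was 8, 1 and 1 without each NUAK548 library and 1, 6 and 11 without each NUAK550 library.

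Whether the change from lacZ to NUAK differed between muscle and whole larvae was tested directly. The test does not separate NUAK from the male signal of the groups. The rise of l(2)efl was larger in muscle, with a difference in log2 fold change of 2.68 (SE 0.19, adjusted p = 1.5e-05). RyR fell in muscle (log2 −2.54) and was not called in whole larvae (log2 1.06, adjusted p = 0.19), a difference of −3.53 (SE 0.63, adjusted p = 0.011). Dscam4 (difference −3.82, SE 0.69, adjusted p = 0.011) fell in muscle, and CG30334 (6.02, SE 1.07, adjusted p = 0.011) and CG14022 (4.19, SE 0.64, adjusted p = 0.0053) rose there, without a call in whole larvae. CG3588 rose in whole larvae and was not called in muscle (−8.35, SE 0.83, adjusted p = 0.0002). It was also far higher in lacZ muscle than in lacZ whole larvae, and whether its difference reflects NUAK was not tested. Nuak itself rose less in muscle (−1.14, SE 0.25, adjusted p = 0.034), where its lacZ level was higher. Of 12429 genes, 254 were called, 139 higher and 115 lower in muscle relative to whole larvae. The median difference over all genes was 0.11, and −0.00818 with library totals alone. Of the called genes 54.7% were higher, against 39.2% with median-of-ratios size factors and 27.1% with library totals alone, so the main direction depends on the scaling.

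Without the first NUAK548 library of whole larvae, the one at the lacZ level of roX1, the count of 254 was 1858. It was 119, 119 and 118 without each lacZ muscle library, 168 and 164 without the second and the third NUAK550 muscle library, 166 without the third lacZ whole library, and 152 and 153 without the first and second NUAK550 whole library.

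In the lacZ controls, most genes differed between muscle and whole larvae, with cuticle genes among the largest rises and a mucin gene among the largest falls. Higher in muscle were CG3588 (log2 10.50, SE 0.82, adjusted p = 3.9e-07), the lectin gene lectin-22C (9.59, adjusted p = 2.2e-05; 2 counts in lacZ whole larvae), the cuticle protein genes Lcp65Aa (6.49, adjusted p = 3.2e-05) and Cpr49Af (5.88, adjusted p = 0.0001), and CG10953 (6.08, adjusted p = 0.0052). Lower were the mucin gene Muc68E (−8.19, adjusted p = 9.4e-06), CG12951 (−8.28, adjusted p = 0.0001), lncRNA:CR9284 (−8.22, adjusted p = 0.002), lncRNA:CR32658 (−8.09, adjusted p = 0.0053) and CG4744 (−8.06, adjusted p = 0.0043), the last 2 with 3 counts in lacZ muscle. Of 12429 genes, 7401 differed, 2789 higher and 4612 lower in muscle, with a median over all genes of −0.21. With library totals alone the median was −0.70, so single directions depend on the scaling. Whole larvae contain the carcass, so rises as large as those of CG3588 and lectin-22C are hard to reach by dissection alone. Whether the larvae of the 2 preparations differed in other ways was not tested.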

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

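The 2 tests of the male share and the testis, both tests of l(2)efl and the second test of the ribosomal proteins were chosen only after the results were seen, while the scaling test of the ribosomal proteins and all splits of the libraries were set beforehand.

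The change from lacZ to NUAK differed between muscle and whole larvae for 254 genes by a test of the difference itself. This test does not separate NUAK from the male signal, in which the groups differed as well. The count was 1858 without the first NUAK548 library of whole larvae and 1294 with the roX1 covariate. As log2 fold change in muscle minus that in whole larvae, the largest were CG30334 at 6.02, CG14022 at 4.19, Rpt6R at 3.70, CG1113 at 2.74 and l(2)efl at 2.68. On the negative side were CG3588 at −8.35, Hsp70Bb at −3.94, Dscam4 at −3.82, RyR at −3.53 and Cyp6a17 at −3.23, with Nuak at −1.14. The lacZ groups of the 2 preparations also differed strongly in CG3588. Rpt6R was not called without the first or the third lacZ muscle library (adjusted p = 0.055 and 0.06). CG1113 was lost without the second or the third lacZ whole library (0.054 and 0.053) or the first or second lacZ muscle library (0.065 and 0.07). Cyp6a17 was lost without any of 14 of the 18 libraries, up to adjusted p = 0.12 without the third lacZ muscle library. Hsp70Bb has near-identical copies in the genome, so its counts are uncertain. As many as 254 genes came from 2 of 100 splits, the real one included, which is under the share of 0.05. The highest other split gave 749, so regrouping the libraries can exceed this count. That other split set the 3 NUAK550 muscle libraries against the rest in muscle, and in whole larvae the second and the third lacZ and the third NUAK548 library against the rest. Another split with the same 3 muscle libraries gave 4, and why the first gave 749 was not tested.

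The first pattern weighed is the lower male signal in whole NUAK larvae. If the larvae of the libraries held different shares of males, the genes lower in NUAK550 should stand high in the first NUAK548 library, the one with the lacZ level of roX1. Of 2257 genes called lower when NUAK550 and lacZ alone were fitted, 1968 (87.2%) were higher in that library than in both other NUAK548 libraries. The share was 31.5% among all 12255 genes and 18.9% among those not called lower. The 754 genes called higher in the same fit did not mirror the 87.2%, as 26.9% of them were lowest in the first NUAK548 library. Loss of testis RNA alone is excluded, since roX1, which marks male cells of every tissue, had a log2 fold change of −3.05 in NUAK550 muscle, a preparation in which the testis gene betaTub85D stood at 0.674 ± 0.502 CPM even in lacZ. A lower share of males in most NUAK samples is consistent with the 87.2% and with roX1, and leaves the higher genes unexplained. Whether the genotype or the picking of larvae set that share was not tested.

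The second pattern is the rise of l(2)efl in NUAK muscle. Of 7 heat shock genes tested, 1 was called higher, Hsp68 (log2 2.54), and the other 6 had log2 fold changes of −0.95 to −0.15 that were not called. This argues against a joint rise of these heat shock genes. It does not exclude a stress response of fewer genes. In the chaperone list, which holds l(2)efl and Hsp68, 4 of 21 genes rose and 0 fell, and fry called it higher (adjusted p = 0.0048). The gene l(2)efl differed between NUAK550 and NUAK548 by log2 0.0106 (SE 0.15) while roX1 differed by −1.96. This argues against a rise in step with the fall of roX1. It cannot exclude the share of males in another form, since roX1 nearly coincides with the groups in muscle. With the roX1 covariate 0 genes were called for the mean there. An effect of NUAK on this chaperone gene stays open as a hypothesis, found and tested on the same libraries.

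The third pattern is the rise of cytosolic ribosomal protein genes in NUAK muscle. The rise does not depend on TMM, as the median log2 fold change was 0.285 with library totals alone. Library totals are relative as well, so a shift in the make-up of the RNA is not excluded as its cause. The share of males cannot be told apart from the effect of NUAK here, because the median in whole NUAK550 larvae was 0.187, between the bounds set for either reading, and in muscle roX1 falls with the groups. A difference in growth between the groups may also contribute and was not tested.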

How the results depend on the processing

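The models with roX1 as a covariate and without the third lacZ and the third NUAK548 library of whole larvae were chosen after the data were seen; the other alternatives were planned. Of 311 values for the counts of genes and lists and for Nuak under all alternatives, 193 kept their direction and side of the threshold, or stayed within 1.5 times for counts. Of 2582 values for 142 results of 126 named genes, 2067 did, 514 kept the direction without being called and 1 turned: Hex-A in muscle, log2 0.0503 with the roX1 covariate. Of the 514, 302 came from leaving out 1 library, 114 from the roX1 covariate, 41 from the replicate block, 14 each from limma-voom and the 2 libraries left out, 9 from no filter, 7 each from library totals and the 2 groups alone, 4 from the authors' values and 1 each from the strict filter and size factors. Counts are given in the order NUAK548, NUAK550, mean and NUAK550 against NUAK548. DESeq2 called 1132, 1880, 1661 and 897 in muscle, 488, 2419, 1250 and 1012 in whole larvae, 824 for the difference between preparations and 669 and 243 shared in muscle and whole larvae; on simulated unchanged genes it made 23 to 29 false calls in muscle and 76 to 79 in whole larvae. With the replicate block, muscle gave 222, 572, 520 and 26, whole larvae 13 for the mean and 10 for NUAK550 against NUAK548, the difference 163, and shared genes 153 and 7. Residuals of libraries with the same number correlated at −0.34 to 0.31 in muscle, where 3 of 9 libraries correlated best with their own number, and −0.06 to 0.37 in whole larvae, where 7 of 9 did. The 3 lacZ and NUAK548 pairs of whole larvae had 0.17, 0.37 and 0.29, so pairing stays open there; their block count was 13 against 19. With the roX1 covariate, muscle gave 18, 0, 0 and 0 (unadjusted p below 0.05: 1241, 360, 579 and 213), whole larvae 5, 1, 3 and 9, the difference 1294, and shared genes 0 and 1; Nuak in NUAK550 muscle was 4.42 and no longer called. In muscle roX1 nearly coincides with the groups, so the 2 are not separable there. With only the 2 groups compared, muscle gave 341 for NUAK548 and 30 for NUAK550 against NUAK548, and whole larvae 6, 3011 and 134 for NUAK548, NUAK550 and NUAK550 against NUAK548. Limma-voom gave 157 for NUAK550 and 2094 for the mean in whole larvae. The authors' values gave 41, 2122 and 31 for NUAK548, NUAK550 and NUAK550 against NUAK548 in whole larvae, and 26 shared. Library totals alone gave 32 for NUAK548 in whole larvae. Without the third lacZ and the third NUAK548 library, whole larvae gave 10, 56, 15 and 32, and 3 shared. No list was called with an estimated correlation in either preparation (0 and 0), and fry called 6 and 1. In muscle fry called cytosolic ribosomal, nucleolar, chaperone and cell cycle genes (adjusted p = 0.006 for the last) higher, and JNK (0.032) and neuromuscular junction genes lower. In whole larvae fry called the nucleolar list higher (adjusted p = 0.0013). The causes were not tested. Leaving out 1 library at a time gave, in muscle, 174 to 398, 403 to 987, 410 to 978 and 27 to 174; in whole larvae 4 to 2271, 12 to 54, 3 to 2721 and 1 to 11; for the difference 118 to 1858; for lacZ muscle against whole larvae 6046 to 7380; for shared genes 134 to 286 and 3 to 2059; for lists 8 to 12 and 10 to 16. The 2271, 2721, 2059 and 1858 are those without the first NUAK548 whole library. Nuak ranged from 2.61 to 2.90 and 3.38 to 3.54 in muscle and from 3.60 to 3.99 and 4.59 to 4.98 in whole larvae. With library totals alone, the share of called genes that were higher went from 51.3% to 30.8% for NUAK550 and from 45.7% to 32.7% for the mean in muscle, from 36.8% to 59.4% for NUAK548 and from 73.7% to 61.0% for NUAK550 in whole larvae, from 54.7% to 27.1% for the difference, and from 37.7% to 15.6% for lacZ muscle against whole larvae. Simulated recovery at 1.5-fold was 10.4% in muscle and 0% in whole larvae, so small changes were mostly not detectable.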

Other observations

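The count of genes called in both preparations was chosen after the results were seen, and the splits of the libraries were planned.

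A set of 21 genes was called for the mean of the NUAK groups in both preparations, 12 higher and 9 lower in both and 0 in opposite directions, among 9678 genes tested in both. Independent lists would share 1.23 higher and 1.58 lower genes. Beside Nuak, mthl8 and l(2)efl, the genes higher in both were GILT3 (log2 2.27 in muscle, 1.98 in whole larvae), CG3630 (1.74, 0.85), NimC1 (1.58, 1.05), uncNacbeta (1.27, 1.06), rtet (1.08, 1.58), hry (0.92, 0.61), CG31676 (0.87, 1.86), tn (0.76, 0.89) and peng (0.44, 0.52). Lower in both were Oseg5 (−3.79, −2.90), CG4757 (−2.15, −4.45), CG12224 (−1.64, −2.55), CG2493 (−1.54, −1.04), Obp56d (−1.36, −1.08), CG15282 (−1.30, −1.95), CG11668 (−1.11, −1.70), CG2211 (−0.85, −0.77) and Sfxn2 (−0.64, −0.60). Without the second lacZ library of whole larvae, 3 genes in all were called there, with the replicate block 13, of which 12 were among the 52, and without any other whole-larva library except the first NUAK548 one, 11 to 25 were. With the roX1 covariate, 3 genes in all were called in whole larvae and 0 in muscle. Most genes of the set of 21 lie outside the naming rule and were chosen after their values were seen.

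Drs and Obp99b had their lowest levels of the whole-larva groups in NUAK548. Drs, an antifungal peptide gene, stood at 36.1 ± 5.41 CPM in lacZ, 2.86 ± 0.657 in NUAK548 and 22.1 ± 7.92 in NUAK550 (mean NUAK log2 −2.18, SE 0.24, adjusted p = 0.016), a call lost without any of 4 libraries, up to adjusted p = 0.086 without the first NUAK550 library, and with the replicate block (0.071). Obp99b, an odorant-binding protein gene of the fat body list, stood at 4492 ± 1311, 163 ± 36.0 and 2905 ± 1576 CPM (log2 −2.70, SE 0.34, adjusted p = 0.027), lost without any of 6 libraries, up to adjusted p = 0.12 without the first NUAK550 library, and with the replicate block (0.067). For the mean of the NUAK groups in whole larvae, the lists of chaperones (camera adjusted p = 0.48), autophagy (0.13), glycolysis (0.058), oxidative phosphorylation (0.92), mitochondrial ribosomal proteins (0.42), lipid synthesis (0.21), muscle identity (0.066), neuromuscular junction (0.096), Hippo (0.46), ecdysone (0.46), immune response (0.46), antioxidant (0.62) and JNK genes (0.46) were not called. Nor were those of fat body (0.81), cuticle (0.46), gut (0.47), salivary gland (0.96), glia (0.42), hemocyte (0.19), trachea (0.12), imaginal disc (0.11) and Malpighian tubule genes (0.39). Some of these lists were called in single groups by camera, without a run at an estimated correlation. The gut list was called lower in NUAK548 (median −0.73, 0 of 45 members called, adjusted p = 0.00027) and higher in NUAK550 (0.44, 0 higher and 1 lower, 0.04). The oxidative phosphorylation list was called lower in NUAK548 (−0.20, 7e-05) and higher in NUAK550 (0.31, 0.0028), and glycolysis higher in NUAK550 (0.60, 9.4e-05), with 0 members called in each. For the mean of the NUAK groups the oxidative phosphorylation list had a median of 0.08 and a mean of −0.79, so some members fell far more than the rest. It had 83 members tested here against 64 in muscle, and whether these members carry the male signal was not tested. Camera also called neuromuscular junction (adjusted p = 0.016), lipid (0.04), cuticle (0.017) and hemocyte genes (0.021) higher in NUAK550, and muscle identity (0.046) and imaginal disc genes (0.01) higher in NUAK548, with at most 2 members called in each. The members called over all genes were 1 higher each for chaperones, antioxidant and hemocyte genes and 1 lower each for immune, cuticle and fat body genes.

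Other splits of the same libraries tested whether regrouping alone gives as many calls. In muscle, 1 of 100 splits, the real one, gave as many as 1041 genes for the mean of the NUAK groups, and the highest other gave 144, with the 3 libraries of NUAK550 set against the rest. The 354 shared genes were reached by 1 of 100, with 32 in the highest other. In whole larvae, 2 of 100 splits gave as many as 52 genes, and the highest other gave 363, with the 3 libraries of NUAK550 set against the rest. Why that split gave more was not tested. The 12 shared genes were reached by 1 of 100, with 6 in the highest other. For these 4 counts the share of splits was under 0.05, though for the 52 genes another split went above the real one. Chance regrouping is not excluded for the lists called by camera, since 44 of 100 splits gave as many as 11 lists in muscle (highest other 19) and 60 of 100 as many as 12 in whole larvae (highest other 21). The median of the other splits was 10 lists in muscle and 12 in whole larvae, close to the real counts. List calls of the single groups were not set beside splits. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In each the real split was the 1 with the most genes (546, 1233, 142, 19, 99, 17 and 7401), and the highest other gave 1 for NUAK548 in whole larvae and 0 elsewhere.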
